A study of Homo sapiens with 8 samples.

How the data were processed

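Signals of each spot came as intensities that the authors made with Agilent Feature Extraction 10.5.1.1 and its protocol GE1_105_Dec08, per the file headers, while the labels print version 10.5.11. Per the file headers, the processed intensity of a spot is its brightness after background subtraction and spatial detrending, with a floor for dim spots and no scaling between arrays. The label protocol names 2 dyes, 1 for each line, but the dye field of all 8 samples names the same dye and each file holds 1 channel, the green one. The arrays were taken as labelled with that dye. If the lines did carry different dyes, the values of TRF2dB minus vector at 0 h would hold a dye difference, while differences from 0 h within a line would not. The series also holds a log2 table deposited by the authors, whose values are differences from the 0 h array of the same line. Its file name speaks of the 75th percentile, but its values correlated at 1.0 with differences after quantile normalization and at 0.84 to 0.98 with differences after scaling to the 75th percentile, across probes of the same arrays. Both 0 h columns of that table hold 0, so it cannot give the comparison of the lines before 4-OHT, and it was used only as an alternative.

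From the deposited intensities, log2 of the processed signal minus the 75th percentile of the array was computed here for 58717 spots that were not controls. Spots marked as outliers were left out, the spots of a probe were averaged, and 107 of 50599 probes dropped out on the way. For a gene with several probes (5749 genes) the probe with the highest mean over the 8 arrays stood for the gene. Gene names came from the files and from a gene table of assembly GRCh38.p14, used for names alone: 28174 probes matched a symbol, 22425 did not and were kept under their own ID, and no coordinates are given, since the array was annotated on hg19. Of the 41101 genes and unnamed features, 20484 had a symbol; the word genes below covers both where all are counted.

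Noise between spots of 1 array was read from the 902 probes printed 10 times. On each array only those with all kept spots well above background were used. The median of their standard deviations was 0.06 to 0.07 log2 over the 8 arrays in the brightest of 3 signal classes. It was 0.10 to 0.13 in the middle class and 0.21 to 0.25 in the dimmest, which held as few as 13 probes on an array. Probes not well above background are not covered. This noise holds no variation between cultures.

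The time trend was tested with limma (lmFit and eBayes, R 4.3.3, limma 3.58.1, data.table in version 1.17.8) as the slope over hours on the 6 TRF2dB arrays, for 32058 genes well above background on at least 2 of them, 17953 of them named. Slopes are in log2 per 60 h, p-values were adjusted by Benjamini-Hochberg, and the threshold was 0.05. The 4 residual degrees of freedom hold both array noise and departure from a straight line. A difference between 2 arrays is given as a value with no test. Genes past 1 log2 were counted among those well above background on at least 1 array of the comparison. A side that was not well above background was raised to the array's lowest signal that was, which gives a bound. Where such a dim side already lay above that signal, its measured value was kept.

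Gene lists were fixed before the data were examined and tested with limma's camera on the slope with a preset correlation of 0.01, and again with an estimated correlation. The lists were interferon-stimulated genes, interferon genes, nucleic acid sensing, cytokine and NF-kB targets, p53 targets, mitotic genes, DNA replication genes, telomere proteins, homologous recombination and damage signalling, the unfolded protein and integrated stress response, cholesterol synthesis, oestrogen receptor targets, extracellular matrix, hypoxia and glycolysis, immediate-early genes, heat shock proteins, autophagy, housekeeping genes, and markers of epithelial cells, leukocytes and endothelial cells. For differences between 2 arrays, the median of a list was ranked among 10000 random lists of the same size and like mean signal, as a description of these arrays. The order test compared Pearson's r and Spearman's rho of a list's mean, or of IFNB1, with hours to the values of all 720 orders of the 6 arrays, two-sided.

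Named genes followed a rule set before the data were examined. It took IFNB1, TERF2 and ESR1; genes past the trend threshold or, as none passed, the 10 with the smallest p in each direction; at 48 h the 10 highest and 10 lowest by the TRF2dB change minus the vector change, of 17 and 13 that differed from 0 h by 1 log2 or more the same way at 36, 48 and 60 h and were well above background on those 3 arrays (the 17) or on the TRF2dB 0 h array and both vector arrays (the 13); the 5 highest and 5 lowest of vector 48 h minus 0 h and of TRF2dB minus vector at 0 h; up to 4 members per list with the largest slope either way; and the 3 highest and 3 lowest differences from 0 h at each time. Not every gene it gave is printed, and some were left out on purpose. RSAD2 and the others among the 12 named genes called with a stricter filter were listed because of that count.

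The trend and list scripts were tried on simulated values for 32058 genes before use. Of 50 genes given a slope of 1 log2 per 60 h, 15 were recovered, and of 50 each with slopes of 2, 3 and 4, 40, 43 and 46, with 10 false calls in all. Of 5 lists shifted by 0.5 log2, 5 were recovered, and 1 of 15 unchanged lists was called. The simulated noise was independent between genes, while the 9 lists called in the data had estimated correlations of 0.09 to 0.80. The trial therefore does not show how often the preset correlation gives false calls for correlated lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.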

Results

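RNA of BJ-5ta cells, a line of human fibroblasts immortalised with telomerase (hTERT), was measured on 8 single-colour Agilent arrays, all on 1 slide. Cells carried either an empty vector (2 arrays) or ERT2-TRF2dB (6 arrays), a form of the telomere protein TRF2 without its basic domain, fused to a receptor part that 4-hydroxytamoxifen (4-OHT) activates. The vector cells were taken at 0 and 48 h of 1 µM 4-OHT, and the ERT2-TRF2dB cells, called TRF2dB cells from here on, every 12 h from 0 to 60 h. There were no replicates: each group had 1 array, although the labels speak of several independent experiments per time. The number of arrays limits the precision of every value.

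Each array held 62976 spots, and no spot was saturated. Of 50492 probes, 77.8% to 82.4% lay well above background on the 4 arrays of slide row 1 (both vector arrays and TRF2dB at 0 and 12 h). On the 4 arrays of slide row 2 (TRF2dB at 24, 36, 48 and 60 h) the share was 69.8% to 71.8%, and the lowest signal counted as well above background was 48.1 to 62.1, against 20.4 to 27.9 in row 1. Late hours and slide row 2 therefore coincide, and for this reason slopes are also given with slide row as a block and over the 4 arrays of row 2 alone. Within row 2 the slide column also rose with hours, from column 1 at 24 h to column 4 at 60 h. Neither setting can therefore separate hours from position along the row.

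The transduced gene was looked at first, as a check of the labels. A probe of ESR1, the oestrogen receptor gene that the ERT2 part comes from, stood on all 6 TRF2dB arrays between 5.62 and 5.91 log2 relative to the 75th percentile of the array (probe A_33_P3379356). On the vector array at 0 h it read -6.53 and was not well above background. By these measured values ESR1 was 5022-fold higher in TRF2dB cells at 0 h, with a dim vector side. A further ESR1 probe (A_24_P383478) read between 0.79 and 1.14 on all 8 arrays and did not set the lines apart, and the remaining ESR1 probe was dim on all 8. TERF2, the gene of TRF2, was 0.17 log2 higher in TRF2dB than in vector cells at 0 h, and its slope over 60 h was 0.06 ± 0.11 log2 (SE; limma adjusted p = 0.851), or -0.07 without the 60 h array. Whether the TERF2 probe lies in the transduced part is not known from the files, so TERF2 checks nothing here.

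IFNB1, which codes for interferon beta, rose with hours of 4-OHT in TRF2dB cells. Its differences from 0 h were 0.25 log2 at 12 h, 0.53 at 24 h, 1.16 at 36 h, 2.31 at 48 h and 3.72 at 60 h, the last a 13.2-fold difference (probe A_23_P71774). In vector cells IFNB1 differed by 0.04 log2 at 48 h. Pearson's r of IFNB1 with hours was 0.947 and Spearman's rho 1.0 over the 6 arrays, each with a two-sided exact permutation p = 0.00278, the smallest that the 720 orders of the arrays can give. Adjusted over the 22 relations tested in this way (IFNB1 and 21 gene lists), the permutation p was 0.0244 for r and 0.0306 for rho, and r without 0 and 60 h was 0.961. This order test was added after the data were seen. In the limma model of all genes, planned before the data were examined, the slope of IFNB1 was 3.63 ± 0.52 log2 per 60 h, which did not pass the threshold (adjusted p = 0.115). The slope was 4.99 ± 0.69 with slide row as a block and 5.37 over the 4 arrays of row 2.

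The question of the time series was how gene expression in TRF2dB cells moves after 4-OHT. Besides IFNB1, the genes that followed hours most closely with a positive slope included IFIT2, IFIH1 and RIGI, which bind or sense viral RNA, the chemokines CXCL10 and CXCL11, and GDF15, a secreted stress protein and p53 target. IFIT2 was 5.52-fold higher at 60 h than at 0 h, CXCL10 12-fold, RIGI 2.86-fold and GDF15 4.33-fold, while CXCL11, dim at 0 h, was at least 24.1-fold higher. THEMIS2, SSTR2, SLC25A28 and CMPK2, a mitochondrial nucleotide kinase induced by interferon, had slopes between 1.07 and 1.49 log2 per 60 h. Among the genes with the smallest p and a negative slope were CPA4, MEST, SYNPO, LRRN4CL and GCAT, with slopes from -1.59 to -0.76. XKR6, SPICE1, C1QL4, LIPI and PKHD1 also belonged there by rule, but each was well above background only on 2 TRF2dB arrays, both in slide row 1.

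None of these genes passed the threshold. With limma, 0 of 32058 genes had a time trend at an adjusted p below 0.05, the smallest adjusted p was 0.108, and 5098 genes (15.9%) had an unadjusted p below 0.05, of which 2692 had a positive slope. Under other settings of the model the count was 114 with the normexp background correction, 25 among genes well above background on all 6 arrays, 869 with intensity-trend and robust variances, and 5 with a square term added. The 12 named genes among the 25 were CXCL10, RSAD2, IFIT2, GDF15, IFIH1, RIGI, SSTR2, CMPK2, THEMIS2 and SLC25A28 with positive slopes, and CPA4 and MEST with negative ones.

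**Figure D1:**
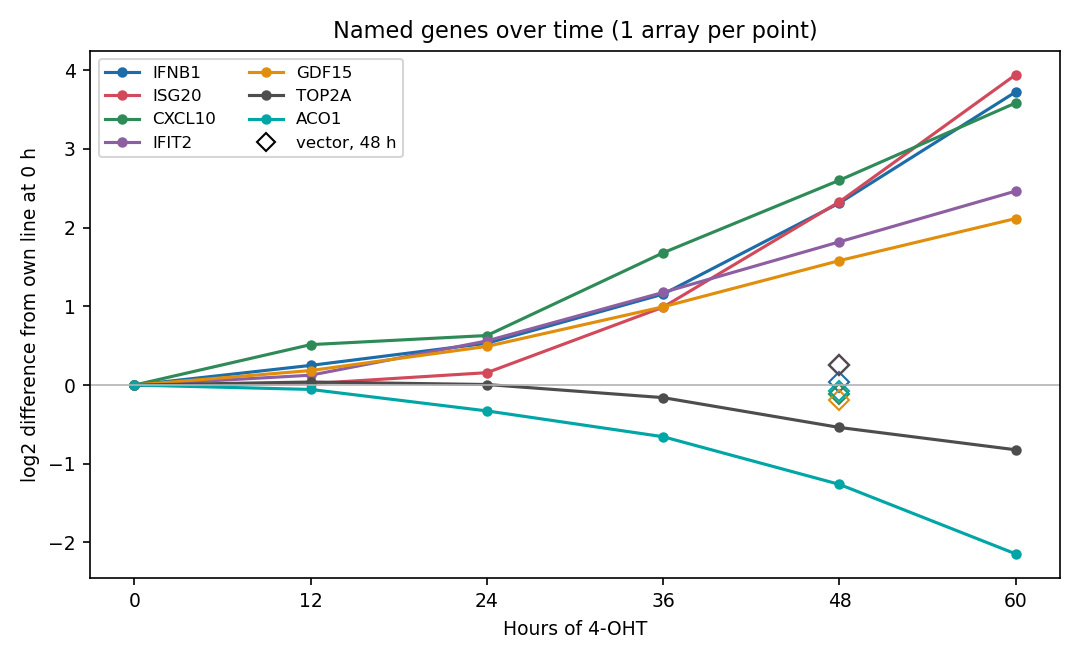
Log2 difference from the 0 h array of the same line (vertical axis) against hours of 4-OHT (horizontal axis) for 7 genes, with 1 array per point. Filled points joined by lines are TRF2dB cells and open diamonds are vector cells at 48 h; IFNB1 reaches 3.72, ISG20 3.94, CXCL10 3.58 and ACO1 -2.14 at 60 h, and the diamonds lie near 0.

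Interferon-stimulated genes rose together in TRF2dB cells: the slopes of all 39 measured members were positive, with a median of 1.01 log2 per 60 h. Their median difference from 0 h was -0.03 log2 at 12 h, 0.15 at 24 h, 0.39 at 36 h, 0.66 at 48 h and 0.94 at 60 h. ISG20, an exonuclease that degrades RNA, was 15.4-fold higher at 60 h, OASL 7.35-fold, and RSAD2, which codes for viperin, 5.46-fold. The list passed camera against all other genes (adjusted p = 3.68e-33), with adjusted p = 0.287 with an estimated correlation between genes. Over all genes 0 members passed, and 37 of 39 passed adjusted over the list alone, all with positive slopes. The median slope was 1.20 with slide row as a block and 1.33 within row 2. The order test gave r = 0.959 (exact permutation p = 0.00556, adjusted 0.0244; r without 0 and 60 h 0.984) and rho = 0.943 (exact permutation p = 0.0167, adjusted 0.0733). In vector cells the list's median difference at 48 h was 0.19, above all of 10000 random lists of like signal.

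Cytokine genes and targets of NF-kB rose as well, with a median slope of 1.04 log2 per 60 h over 33 measured members, 31 of them positive. The median difference was 0.04 log2 at 24 h, 0.41 at 36 h, 0.80 at 48 h and 1.01 at 60 h, and 17 members were higher by 1 or more at 60 h. CXCL8 and CXCL1, which attract neutrophils, were 5.96-fold and 4.25-fold higher at 60 h. The camera test passed (adjusted p = 1.17e-16; adjusted p = 0.287 with an estimated correlation), and 23 of 33 members passed adjusted over the list alone, 14 without the 60 h array, against 0 over all genes. With slide row as a block the median slope was 1.46, and within row 2 it was 1.65. The order test gave r = 0.964 and rho = 1.0, each with an exact permutation p = 0.00278 (adjusted 0.0244 and 0.0306), and r without 0 and 60 h was 0.968.

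Genes that sense nucleic acids rose by a median slope of 0.55 log2 per 60 h, with 16 of 19 slopes positive. AIM2, a sensor of DNA in the cytosol, was 11-fold higher at 60 h, TLR3 2.94-fold, ZBP1 2.36-fold and MYD88, an adaptor of Toll-like receptors, 2.08-fold. The list passed camera (adjusted p = 2.92e-08; adjusted p = 0.287 with an estimated correlation). Adjusted over the list alone, 13 members passed with positive slopes and 1 with a negative slope; the counts were 8 and 0 without the 60 h array and 11 and 0 without the 12 h array. The median slope was 0.66 with slide row as a block and 0.77 within row 2, and the order test gave r = 0.946 (exact permutation p = 0.00556, adjusted 0.0244; 0.973 without 0 and 60 h) and rho = 0.943 (exact permutation p = 0.0167, adjusted 0.0733). The separate list of interferon genes, with 10 of its members measured, did not pass (median slope 0.26, camera adjusted p = 0.132). IFNB1 alone passed there adjusted over the list alone, and 2 genes passed without the 0 h array or with the normexp background correction. IFNA2 and IFNL1 were highest at 36 and 48 h with differences of 2.67 and 1.28, and IFNA21 was 0.83 higher at 60 h.

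Targets of p53 rose by a median slope of 0.31 log2 per 60 h, with 26 of 30 slopes positive. Beside GDF15, CDKN1A, an inhibitor of cell cycle kinases, was 1.77-fold higher at 60 h, TIGAR 1.84-fold and PLK3 1.69-fold. The list passed camera (adjusted p = 1.64e-07; adjusted p = 0.447 with an estimated correlation), and 10 members passed with positive slopes and 1 with a negative slope (ZMAT3, 0.36 lower at 60 h) adjusted over the list alone. The count of positive slopes was 6 without the 0, 24 or 36 h array, 4 without 12 h, and 1 without 48 or 60 h; that of negative slopes was 1 without 0 h, and 0 without any other array or with slide row as a block. The median slope was 0.51 with slide row as a block and 0.48 within row 2. The order test gave r = 0.897 (exact permutation p = 0.00556, adjusted 0.0244; r without 0 and 60 h 0.857) and rho = 0.943 (exact permutation p = 0.0167, adjusted 0.0733).

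Genes of the unfolded protein and integrated stress response rose by a median slope of 0.28 log2 per 60 h, with 17 of 21 slopes positive. DDIT3 and ATF3, transcription factors induced by stress, were 2.24-fold and 1.79-fold higher at 60 h, CHAC1 2.22-fold and SESN2 1.73-fold. The list passed camera (adjusted p = 2.21e-05; adjusted p = 0.462 with an estimated correlation). Adjusted over the list alone, 6 members passed, 2 without the 0 or 48 h array and 0 without 60 h, where the median slope was 0.13. The median slope was 0.58 with slide row as a block and 0.61 within row 2. In order the list did not pass after adjustment (r = 0.860, exact permutation p = 0.0278, adjusted 0.0815; rho = 0.829, exact permutation p = 0.0583, adjusted 0.160; r without 0 and 60 h 0.499).

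Hypoxia and glycolysis genes had lower medians than at 0 h at 12, 24 and 36 h (-0.09, -0.13 and -0.04 log2) and higher ones at 48 and 60 h (0.20 and 0.41), with a median slope of 0.55 that passed camera (adjusted p = 5.38e-06; adjusted p = 0.462 with an estimated correlation). BNIP3, a mitochondrial protein, was 1.82-fold higher at 60 h, ANKRD37 1.85-fold, EGLN3, an oxygen-sensing hydroxylase, 1.91-fold, and CA9 2.35-fold. The slope of CA9 was 0.91 ± 0.59, and -0.20 without the 60 h array. Of 17 members 0 passed adjusted over the list alone, 9 without the 0 h array, 1 without 24 or 36 h, and 10 within row 2. The order test did not pass after adjustment (r = 0.778, exact permutation p = 0.0611, adjusted 0.117; rho = 0.600, exact permutation p = 0.242, adjusted 0.354; r without 0 and 60 h 0.829), and the list's median slope was 0.22 without 60 h, 0.83 with slide row as a block and 1.05 within row 2.

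Mitotic genes fell in TRF2dB cells: all 32 measured slopes were negative, with a median of -0.65 log2 per 60 h. Their median difference was -0.06 log2 at 36 h, -0.37 at 48 h and -0.65 at 60 h, while in vector cells it was 0.28 at 48 h. KIF20A, a kinesin of cell division, was 2.02-fold lower at 60 h, DLGAP5 1.85-fold, CENPA, the histone of centromeres, 1.77-fold, and TOP2A, a topoisomerase, 1.77-fold. The list passed camera (adjusted p = 2.32e-16; adjusted p = 0.462 with an estimated correlation). Adjusted over the list alone, 17 of 32 members passed with negative slopes, and 0 without the 12, 48 or 60 h array, where the median slope was -0.66, -0.62 and -0.42. With slide row as a block the median slope was -1.11, within row 2 it was -1.18, and the order test did not pass after adjustment (r = -0.852, exact permutation p = 0.0306, adjusted 0.0815; rho = -0.829, exact permutation p = 0.0583, adjusted 0.160; r without 0 and 60 h -0.816).

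DNA replication genes also fell, with a median slope of -0.32 log2 per 60 h and 31 of 32 slopes negative. The median difference was -0.14 log2 at 48 h and -0.40 at 60 h, against 0.18 in vector cells at 48 h. CCNE2, a cyclin of S phase entry, was 2.12-fold lower at 60 h, UHRF1 1.97-fold, MCM6, part of the replicative helicase, 1.91-fold, and RRM2 1.87-fold. Camera passed (adjusted p = 1.06e-07; adjusted p = 0.50 with an estimated correlation), 1 member passed adjusted over the list alone, 0 without any of the 6 arrays and 6 with slide row as a block, and the median slope was -0.12 without 60 h, -0.74 with slide row as a block and -0.76 within row 2. Its order test did not pass after adjustment (r = -0.742, exact permutation p = 0.0639, adjusted 0.117; rho = -0.543, exact permutation p = 0.297, adjusted 0.385; r without 0 and 60 h -0.412). Genes of homologous recombination and damage signalling had a median slope of -0.13 (camera adjusted p = 0.0148; adjusted p = 0.462 with an estimated correlation), -0.25 with slide row as a block and -0.29 within row 2. That call was lost without the 60 h array (median slope -0.06, camera adjusted p = 0.108), and the order test did not pass after adjustment (r = -0.844, exact permutation p = 0.0333, adjusted 0.0815; rho = -0.714, exact permutation p = 0.136, adjusted 0.296; r without 0 and 60 h -0.760). Of its members FANCD2 was 0.58 lower, FANCA 0.81 lower and CLSPN 0.66 lower at 60 h, BRCA2 was 0.73 higher, and 0 of 28 passed adjusted over the list alone.

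**Figure D2:**
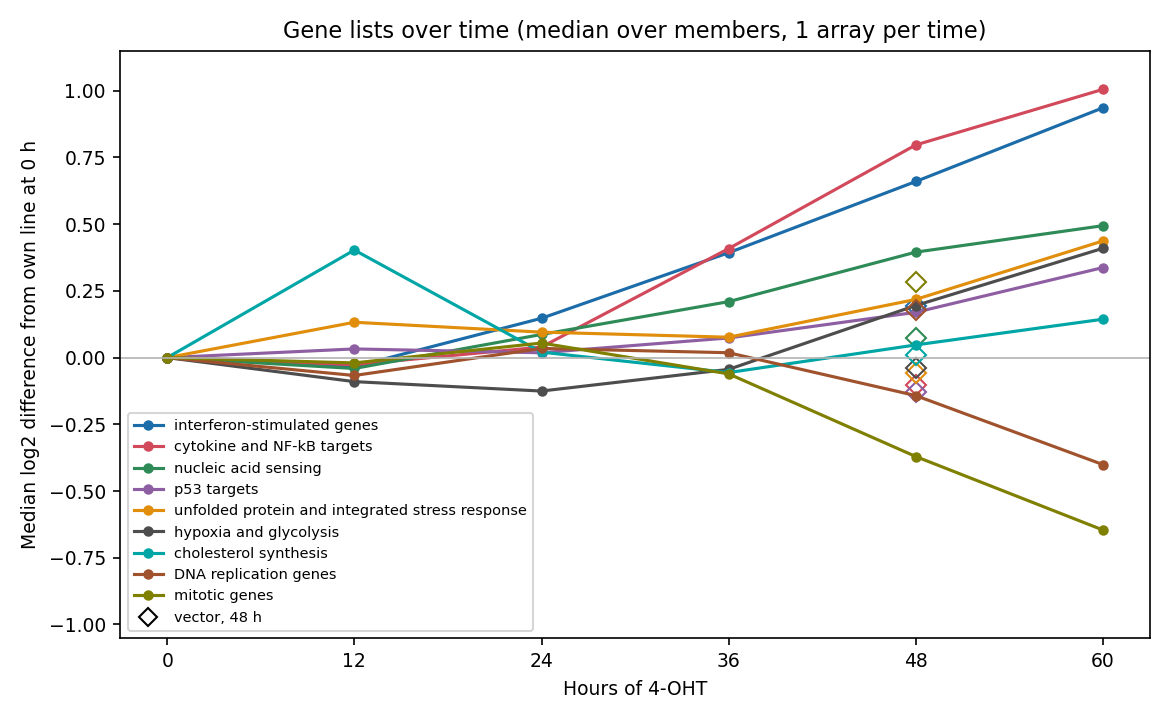
Median log2 difference from the 0 h array of the same line (vertical axis) against hours of 4-OHT (horizontal axis) for 9 gene lists, with 1 array per time. Filled points joined by lines are TRF2dB cells and open diamonds are vector cells at 48 h; at 60 h the cytokine list lies at 1.01, the interferon-stimulated genes at 0.94 and the mitotic genes at -0.65.

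The other lists did not pass camera over time. Telomere proteins had a median slope of 0.03 log2 per 60 h and a mean of 0.00 (adjusted p = 0.904), with DCLRE1B, a nuclease at telomeres, 0.66 lower and TINF2, a shelterin protein, 0.50 higher at 60 h. Oestrogen receptor targets, included because 4-OHT binds that receptor, had a median slope of 0.03 (adjusted p = 0.850), with AREG, a growth factor, 0.85 higher and TFF1, a secreted peptide, 0.53 lower at 60 h; both passed adjusted over the list alone, and 0 of the list did without the 0, 12 or 36 h array or with slide row as a block. Extracellular matrix genes had a median slope of -0.08 (adjusted p = 0.129), where COL3A1 and COL1A1, fibrillar collagens, were 0.60 and 0.52 lower and CCN2 was 0.48 higher at 60 h. The slopes had a median of 0.10 for heat shock proteins (adjusted p = 0.0969; -0.03 with slide row as a block), 0.05 for immediate-early genes (0.0671), 0.07 for autophagy (0.132) and -0.01 for housekeeping genes (0.783). With slide row as a block 4 further lists passed camera: cholesterol synthesis (median 0.53, adjusted p = 1.28e-04), autophagy (0.28, adjusted p = 0.00206), immediate-early genes (0.17, adjusted p = 0.0116) and endothelial markers (0.26, adjusted p = 0.0370).

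Markers of other cell types were looked at over time, which can show a change in foreign cells but not a constant share of them. Epithelial markers had a median slope of -0.10 and a mean of 0.01 log2 per 60 h (camera adjusted p = 0.904), endothelial markers a median of 0.00 and a mean of 0.11 (0.478), and leukocyte markers a median of 0.17 (0.375). KRT14 and DSP, epithelial genes, were 0.95 and 0.80 higher at 60 h, PECAM1, an endothelial gene, 0.61, and CD68 and FCER1G, leukocyte genes, 1.27 and 0.69. KRT18 and CLDN4, also epithelial, were 0.43 and at least 0.72 lower, where CLDN4 was well above background on 3 of 6 TRF2dB arrays but not at 60 h, and CD14, a leukocyte gene, had a slope of -0.30 ± 0.22. Adjusted over each list alone, 2 epithelial genes passed up and 2 down, 2 leukocyte genes up and 0 down, and 0 endothelial genes. These calls changed with the arrays used: the leukocyte count was 2 without the 36 h array and 0 without any other or with slide row as a block, the epithelial count down was 0 without 12, 24, 36 or 60 h, and 0 epithelial genes passed either way without 60 h or with the block. The slope of KRT14 by its other probe was -0.39 instead of 0.85.

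At 12 h of 4-OHT, cholesterol synthesis genes had the largest median difference from 0 h among the lists in TRF2dB cells, 0.40 log2, above all of 10000 random lists of like signal. The median was 0.13 for the unfolded protein and integrated stress response (above 99.98%) and 0.15 for immediate-early genes (above 99.84%). ACAT2, which makes acetoacetyl-CoA, was 0.41 log2 higher and STARD4, a carrier of cholesterol, 0.04. The median of the cholesterol list was 0.02 at 24 h and -0.06 at 36 h (above 2.04% of the random lists). At 48 h it was 0.05 in TRF2dB cells and 0.01 in vector cells, and no vector array was taken at 12 h. Over all 6 TRF2dB arrays the list's median slope was -0.004 with a mean of 0.02 (camera adjusted p = 0.930). The list was higher again later: its median was 0.14 at 60 h (above 97.2% of the random lists), 0.21 at 60 h against 24 h (above 99.99%), and its median slope within row 2 was 0.35 (above 99.98%). Among genes well above background on both arrays, WDR11-DT was 4.69 and MS4A6A 3.67 log2 higher at 12 h, and LRRC61 and LCE3C were 3.53 and 3.25 lower. At 12 h 339 genes were higher and 280 lower than at 0 h by 1 log2 or more.

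By 60 h, the iron-sulphur enzyme ACO1 was 4.42-fold lower than at 0 h, LRRC17 3.78-fold and CCDC13 4.23-fold, and ACO1 was already 1.26 log2 lower at 48 h. The highest values among genes well above background on both arrays were of PCDHGC4 at 24 h (4.08 log2), ARHGAP15 at 36 h (3.91), OR6C76 at 48 h (4.03) and UGT1A6 at 60 h (4.54), and PCDHGC4 and UGT1A6 were dim on 4 of the 6 TRF2dB arrays. RPL34-DT was among the lowest at 12, 24, 36 and 48 h, with values from -1.98 to -1.56. Differences of 1 log2 or more against 0 h were higher for 718 genes and lower for 112 at 24 h, 831 and 104 at 36 h, 764 and 122 at 48 h, and 1144 and 235 at 60 h. These counts raise a dim side to the lowest signal counted as well above background where it lies below that, which hides lower values in slide row 2. With measured values and no such floor they were 736 and 879 at 24 h, 845 and 670 at 36 h, 780 and 988 at 48 h, and 1152 and 1038 at 60 h. With the floor, 1085 named genes were higher by 1 log2 or more at any of the 5 times. Of these, 871 were so at 1 time only and 17 at all of 36, 48 and 60 h. Of 173 named genes that were lower at any time, 136 were so at 1 time only and 22 at all of 36, 48 and 60 h. Each difference compares 2 arrays, has no replicate check and no test, and all 5 times share the 0 h array.

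**Figure D3:**
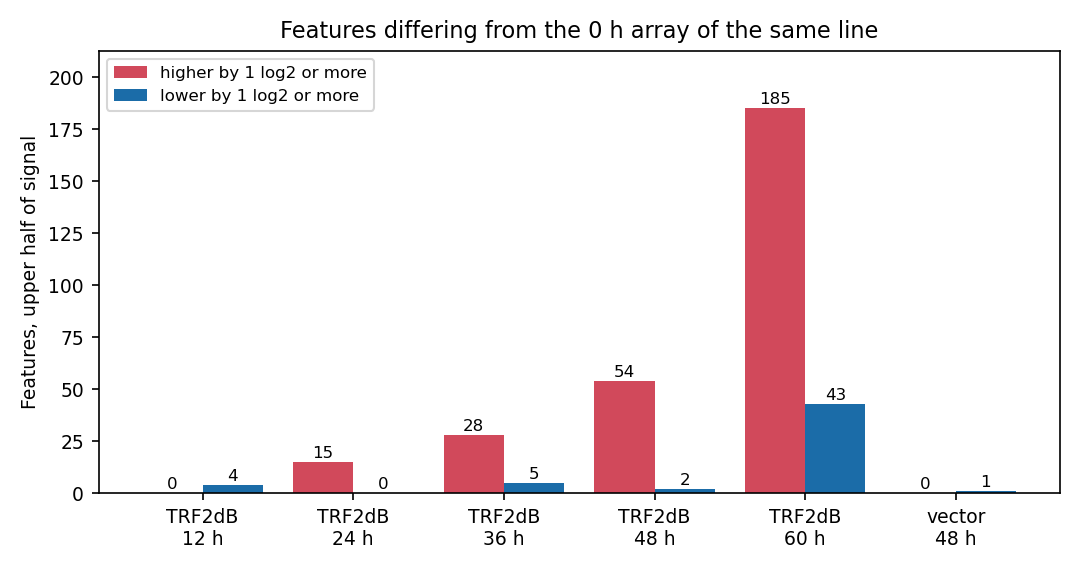
Number of genes and unnamed features (vertical axis) that were higher or lower by 1 log2 or more than on the 0 h array of the same line, among the 16029 features with a signal above the median, for each time and for vector cells at 48 h (horizontal axis). The bars show 15 higher and 0 lower at 24 h, 54 and 2 at 48 h, 185 and 43 at 60 h, and 0 and 1 in vector cells.

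Vector cells had 1 array each at 0 and 48 h of 4-OHT, and their difference was not tested for any gene. At 48 h WDR86, LHFPL3-AS2, VHRT, GALNT13 and KCNK7 were 1.79 to 2.93 log2 higher than at 0 h, and CAGE1, DISP3, H2BP1, MMP7 (a matrix protease) and SERPINA1 (a protease inhibitor) were 1.63 to 3.45 lower. Mitotic genes had a median difference of 0.28 log2, interferon-stimulated genes 0.19, DNA replication genes 0.18, p53 targets -0.13, extracellular matrix genes -0.12 and cytokines -0.10. Each was above or below all of 10000 random lists of like signal. Counts of genes past 1 log2 were 255 higher and 244 lower, or 758 and 274 with measured values. The standard deviation of this difference over genes well above background on both arrays was 0.26 log2.

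The change in TRF2dB cells minus the change in vector cells at 48 h is the comparison that the series design names as its main one. IFNB1 had a value of 2.27 log2, or 1.90 with the normexp background correction, CXCL10 2.72, CXCL8 2.73, GDF15 1.77 and ISG20 2.07. By the rule for this comparison the highest were CXCL11 (at least 16.8-fold), HCN4 (at least 14.5-fold in TRF2dB cells, and dim in vector cells at both times), ARHGAP15, GTF3C2-AS1, CXCL8, CXCL10, LRRC4B, LINC01095, IFNB1 and ZBED3-AS1. List medians were 0.93 log2 for cytokines and NF-kB targets, 0.52 for interferon-stimulated genes, 0.35 for nucleic acid sensing, 0.35 for the unfolded protein and integrated stress response, 0.34 for p53 targets, -0.31 for DNA replication and -0.64 for mitotic genes, each above or below all of 10000 random lists.

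The lowest by that rule were LRRC61, CUX2, TRIM72, OR8K1, LINC00221, SH3RF3-AS1, CCDC13, LINC01132, SOX12 and RPL34-DT. Of these 10 genes, 7 were already lower by 1 log2 or more at 12 h and higher by 1 or more in TRF2dB than in vector cells at 0 h, so that they stood high on the single TRF2dB 0 h array. In all, 1050 genes were higher and 567 lower by 1 log2 or more, and 1253 and 1909 with measured values. The comparison rests on 4 arrays, 1 per line and time, and was not tested. Of these, only the TRF2dB array at 48 h lay in slide row 2. Subtracting the vector change therefore cannot remove a difference between the slide rows.

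Before 4-OHT, TRF2dB cells already differed from vector cells. CKB, a creatine kinase, was 5.93-fold lower, MAGEA12, a gene of the cancer-testis group, 6.97-fold, and H2BP1 and PNMA8A were 3.07 and 2.63 log2 lower, while LRRC61, LINC00221, TRIM72, CREG2 and SH3RF3-AS1 were 1.64 to 2.02 log2 higher. Interferon-stimulated genes had a median 0.39 log2 higher in TRF2dB cells at 0 h, nucleic acid sensing genes 0.23 and cytokines and NF-kB targets 0.21, each above all of 10000 random lists, and IFNB1 was 0.93 log2 higher. Genes past 1 log2 were 226 higher and 534 lower, or 478 and 753 with measured values. This comparison of 1 array with 1 array was not tested either, and a difference of dye between the lines, which the label protocol names and the dye field of the samples does not, was not excluded.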

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

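The tests weighed here were all chosen after the results they measure were seen, except the test of other orders of the arrays for all genes, which was set before.

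At 48 h, some gene lists had medians of opposite sign in the 2 lines, with 1 array per line and time, and these differences between the lines were not tested. Only the TRF2dB array at 48 h lay in slide row 2, so line and slide row are not separated in them. The TRF2dB change minus the vector change had a median of 0.93 log2 for cytokine and NF-kB targets (0.80 in TRF2dB cells, -0.10 in vector cells), 0.34 for p53 targets (0.17 and -0.13) and 0.35 for the unfolded protein and integrated stress response (0.22 and -0.06). It was -0.64 for mitotic genes (-0.37 and 0.28) and -0.31 for DNA replication genes (-0.14 and 0.18). The signs were also opposite, with smaller differences between the lines, for homologous recombination and damage signalling (-0.09 and 0.10), hypoxia and glycolysis (0.20 and -0.04), oestrogen receptor targets (0.08 and -0.05) and further lists with a median about 0.02 or less from 0 in 1 line. Of single genes, CXCL11 had a value of at least 4.07, from at least 2.99 higher in TRF2dB cells and at least 1.08 lower in vector cells.

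Interferon-stimulated genes stood higher at later hours in TRF2dB cells. A difference between the slide rows cannot be the whole of it. Within the 4 arrays of row 2 the list's median slope was 1.33 log2 per 60 h, and random lists of like signal lay between -0.24 and 0.05. Position along the row is not excluded, since within row 2 the slide column rises with hours. Of 100 orders drawn from 360 (an order and its reverse counted once), only the real one gave a median slope as far from 0 (1.01). The highest of the others gave 0.993. In the test of all 720 orders, r passed after adjustment (exact permutation adjusted p = 0.0244) and rho did not (exact permutation adjusted p = 0.0733). Chance in the order of the arrays is therefore unlikely for this list but not excluded. An effect of 4-OHT itself, or of time in culture, stays open in part: the list's TRF2dB change minus vector change at 48 h was 0.52 (random lists -0.02 to 0.13), but it rests on a single vector array at 48 h, in slide row 1, where the TRF2dB array at 48 h lay in row 2. A response to the activated TRF2dB protein may account for the remaining pattern, as a hypothesis found on these same arrays. The list's median was already 0.39 log2 higher in TRF2dB than in vector cells at 0 h, before 4-OHT. Whether that earlier difference bears on the later rise was not tested.

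From 24 h on, more genes were higher than lower against 0 h. Over all genes the floor for dim signals, which lay higher in slide row 2, may account for this: with measured values the mean share of higher genes was 49.5% over the 4 late times. Among genes well above background on both arrays, where no floor acts, the share was still 83.9% to 93.7%. That filter also drops genes that fell below the higher limit of slide row 2, so over all genes the question stays open. Among the 16029 genes above the median signal the floor is excluded, as the lowest share over the 4 late times was 81.1% with measured values. A 0 h array that is low by itself cannot account for it either, as the lowest share against the 12 h array was 81.8%. Both reference arrays lie in slide row 1, so a shift that they share is not excluded for these genes. Within slide row 2, 151 such genes were higher and 58 lower at 60 h than at 24 h, while at 24 h itself slide row and time coincide, and no biological explanation was tested.

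Mitotic genes stood lower at later hours in TRF2dB cells. Within slide row 2 their median slope was -1.18 log2 per 60 h (random lists -0.22 to 0.13), which argues against a difference between the slide rows as the whole cause. Position along the row is not excluded, since within row 2 the slide column rises with hours. Time in culture acting alike in both lines would lower them in vector cells too, where their median difference at 48 h was 0.28 (random lists -0.04 to 0.05), but this is 1 array and cannot be told apart from chance variation between cultures. Slower division after activation of TRF2dB may account for the pattern, as may a difference in cell density between cultures, which no label gives, and neither was tested.

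For the count of genes with an unadjusted p below 0.05, 100 orders of the 6 TRF2dB arrays were drawn from 360. Of these 100, only the real one gave as many (5098), and the highest of the others gave 4516. A share of 1 in 100 is below the 0.05 level, and it is the lowest that 100 orders can give. The orders that were not drawn were not looked at, so the result holds for the drawn ones only. The order that gave 4516 put the 24 h array first and kept the rest in sequence. Late hours and slide row 2 coincide in the real order and in that one, apart from the 24 h array. In the real order the slide column also rises with hours within each row. The test of orders therefore cannot tell hours from position on the slide.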

How the results depend on the processing

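Slide row, row 2 alone, the floor and the measured values were alternatives chosen after seeing the data; the others were planned. No paired analysis was possible because each group has 1 sample and the groups share only the number 1. A slide or scan day block was not run, since all arrays share 1 slide and 1 scan. The normexp correction used median signals, as the files hold no mean signals. Signal over background limits all values of dim genes in slide row 2. The cause was not tested for any change below, except that stricter filters and the estimated correlation act by their construction.

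The count of 0 genes with a time trend stayed 0 with quantile normalization, no filter, the mean of probes, the authors' table, all 8 arrays, slide row as a block, row 2 alone, the floor, and without each array in turn. It was 114 with normexp, 25 with genes well above background on all 6 arrays, 869 with intensity-trend and robust variances, and 5 with a square term. IFNB1 kept its direction throughout, from 2.77 to 4.37 without each array in turn, and passed with normexp (2.89, adjusted p = 0.0477) and with trend and robust variances (3.63, adjusted p = 0.0101); over its alternatives the adjusted p ran from 0.0101 to 0.434. Its value against vector cells at 48 h was 1.90 with normexp.

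Counts past 1 log2 at 12, 24, 36, 48 and 60 h were 127, 495, 484, 525 and 766 with normexp, 1201, 1631, 1554, 1660 and 2164 in the authors' deposited table, and 1156, 1615, 1515, 1768 and 2190 with measured values. Among genes well above background on both arrays they were 299, 491, 569 and 537 at 12, 24, 36 and 48 h. From 24 h on the share of higher genes was over 90% with normexp, and between 42.9% and 49.0% in the deposited table. It was between 83.9% and 93.7% among genes well above background on both arrays. For vector 48 h minus 0 h the counts were 73 with normexp, 199 well above on both, 989 in the table and 1032 measured; quantile normalization gave 226 higher and 403 lower. For the TRF2dB change minus the vector change they were 634, 719, 3192 and 3162, of which 86.6%, 74.3%, 43.3% and 39.6% were higher. At 0 h, TRF2dB minus vector gave 223 with normexp, 459 well above on both and 1231 measured.

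Of 9 lists called by camera, 0 were called with an estimated correlation, where the median slopes are by construction the same: 1.01 for interferon-stimulated genes, 1.04 for cytokines, 0.55 for nucleic acid sensing, 0.31 for p53 targets, 0.28 for the unfolded protein response, 0.55 for hypoxia, -0.65 for mitotic genes, -0.32 for DNA replication and -0.13 for homologous recombination. Without each array in turn 8 to 12 lists were called; homologous recombination ranged from -0.18 to -0.063 and lost its call without 60 h.

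Some lists and genes that were not called turned: genes by the sign of the slope, lists by the direction of camera, so the median slope printed for a list can keep its sign. It did so for housekeeping genes, oestrogen receptor targets and telomere proteins with the block, normexp, the floor or no filter, and for cholesterol synthesis with quantile normalization. With slide row as a block cholesterol synthesis had 0.53, heat shock proteins -0.033, housekeeping genes -0.024, ATG4B -0.26, TEK 0.88, OCLN -0.70, CD3E 0.47 and CD14 0.089. Over row 2 alone ATG4B had -0.37, TEK 0.89, OCLN -0.78, CD3E 0.83 and CD14 0.0054. With normexp epithelial markers had 0.11, telomere proteins 0.023, ESR1 0.11, SPICE1 0.093 and TEK 0.054. With the floor epithelial markers had 0.31, oestrogen receptor targets 0.029, telomere proteins 0.030, XKR6 0.046, SPICE1 0.50, C1QL4 0.73 and LIPI 0.29. With no filter oestrogen receptor targets had 0.027 and telomere proteins 0.030, and with quantile normalization cholesterol synthesis had -0.042. By another probe ESR1 had 0.19, ATG4B -0.29 and KRT14 -0.39. Without each array in turn the lowest and highest values were -0.19 and 0.14 for cholesterol synthesis, -0.14 and 0.053 for epithelial markers, -0.0019 and 0.050 for oestrogen receptor targets, 0.011 and 0.034 for telomere proteins, -0.066 and 0.17 for TERF2, -0.53 and 0.044 for TEK, -0.20 and 1.52 for CA9 and -0.81 and 0.31 for CD3E. Of all values of single genes and uncalled lists under settings other than leaving out an array, 1064 kept their side and direction, 79 came to pass a threshold, 63 moved and 31 turned.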

Other observations

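The comparison within slide row 2 was chosen after the data were seen, and the values below carry no test.

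Within slide row 2 alone, 60 h against 24 h gave 736 genes higher and 613 lower by 1 log2 or more with the floor for dim signals. With measured values 151 were higher and 58 lower among genes above the median signal, and 972 and 728 among those below it. IFNB1 was 9.15-fold higher at 60 h than at 24 h, ISG20 13.8-fold, AIM2 9.54-fold and CXCL10 7.75-fold, while ACO1 was 3.52-fold lower. This difference, like the others not tested, uses neither the 0 h array nor arrays of both slide rows. MYB, a transcription factor on the list of oestrogen receptor targets, was 1.86 log2 higher at 60 h than at 0 h, and EGR3, an immediate-early gene, was 0.99 lower.

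Of 14 housekeeping genes 0 passed adjusted over the list alone. RPLP0, a ribosomal protein gene, was 0.50 log2 lower and B2M, part of the class I antigen complex and known to respond to interferon, 0.49 higher at 60 h, while the median difference of the list was -0.02.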
